A study of Mus musculus with 9 samples.

How the data were processed

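Mouse CD4+ T cells were profiled by RNA sequencing in 9 libraries that fall into 3 groups of 3, and each group was taken from the sample titles. Naive wild-type (WT) cells were sorted from lymph node and spleen by surface markers as CD4+ cells negative for CD44 and for a green fluorescent reporter of Foxp3. Activated WT cells and activated cells of the BMPR1a/CD4cre line, called the knockout here, came from lymph node and spleen cells cultured for 3 days with 2 ug/ml of the T cell mitogen ConA and 10 ng/ml of LPS, after which CD44-positive, reporter-negative CD4+ cells were sorted by surface markers. All mice are labelled C57BL/6. Nothing in the labels says that the replicates came from separate mice or cultures, so the p-values measure only the spread between these libraries, part of which may be technical.

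The values are FPKM (fragments per kilobase of transcript and per 1e6 mapped fragments), which the authors deposited as 1 table with a column per library. Per the submitters' processing notes, the tools were TopHat2, Cufflinks and Cuffdiff with genome build GRCm38. Their versions, the gene annotation, the strand setting and the treatment of multiply mapped reads are not given in the sources used here. The lowest values are far below what a single read would be worth in any library, so the FPKM values are fractional estimates and the number of reads behind a library or a gene is unknown. No counting interval or detection floor was therefore computed, and a value of 0 is described only as listed at 0. Without a strand setting, reads of overlapping genes on opposite strands cannot be told apart, and genes with near-identical copies are uncertain. FPKM estimates of very short genes are unstable: the row with the highest FPKM in the table, whose identifier had no symbol in the name table, made up between 5.17% and 48.6% of a library's FPKM sum, and these sums ran from 3446200 to 13114000. The sums over protein-coding genes were close to each other, from 533140 to 595890. Median-of-ratios size factors computed from the 11555 genes at or above 1 FPKM in all 9 libraries lay between 0.970 and 1.035. They were 0.971, 0.973 and 0.982 in the activated WT libraries and 1.035, 1.017 and 1.035 in the knockout libraries, so these groups did not overlap. The main tests used the values unscaled.

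The table holds 25759 gene rows, separated by as many blank lines, and 24876 of the identifiers matched a gene symbol. Chromosomes, positions and gene types come from the GENCODE annotation of GRCm38. No pair of libraries shared more than 2 identical values above 0 among its genes, and the Pearson correlation of log2(FPKM + 1) across tested genes was 0.911 to 0.934 within groups.

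The comparisons were fixed before the data were examined: activated WT with naive WT, activated knockout with activated WT, and, as a secondary comparison in which genotype and activation differ together, activated knockout with naive WT. Genes with a mean of at least 0.5 FPKM over the 9 libraries were tested, which left 15126. Each was tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, by the empirical Bayes moderated test with an intensity trend, in 1 fit of all 9 libraries with group means and no other covariate. The tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes at low levels. A group's value is given as mean ± SD over its 3 libraries. Single values were also compared by a two-sided exact permutation test, whose smallest possible p for 3 against 3 libraries is 0.1.

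Before the data were examined, 47 gene lists were fixed for pathways, T cell states, helper lineages, metabolism, stress responses, markers of other cell types and technical checks. Of their 659 symbols, 642 were in the table. The 45 lists with at least 3 tested genes entered limma's camera test with a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the lists. The test was repeated with a correlation estimated for each list. Its median over the lists was 0.26, and then no list passed in any comparison. For members of a list, the count of calls over all tested genes is given and, where it differs much, the count adjusted over the list alone.

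The genes named in the text follow a rule also fixed beforehand. Bmpr1a was named throughout. For the first and the second comparison, the 8 called genes with the largest positive and the 8 with the largest negative log2 fold change were taken, if every library of one group lay above every library of the other and the higher group had a mean of at least 5 FPKM. Predicted genes, unnamed complementary DNA clones, small RNA genes and antigen receptor segments were left out. Up to 3 called members at that level were added from each of the 8 lists with the smallest camera p, lists of other cell types and technical lists not counted, and from both lists of BMP signalling, and any member of a fixed list was allowed where that list is described. Genes outside the rule are said to be chosen after their values were seen.

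The steps were tested on simulated data in which 200 of the 15126 genes had been changed. The changed genes were drawn from those with a mean log2(FPKM + 1) of at least 2. Each comparison had 1 data set, in which genes varied independently with normal errors. Recovery of genes at lower levels or with changes under 1 on the log2 scale was not simulated. For activated WT against naive WT, 77% of the genes changed by 1 on the log2 scale and 96% of those changed by 2 were called. The shares were 80% and 90% for activated knockout against activated WT, and 86% and 91% for activated knockout against naive WT. False calls made up 4.95%, 6.59% and 3.28% of the calls.

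Alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, no filter and a filter at a mean of 2 FPKM, median-of-ratios scaling, quantile normalization, a fit of only the 6 libraries compared, array quality weights, limma without the intensity trend, the replicate number as a block, camera with estimated correlations, and each library left out in turn. Alternatives chosen after seeing the data were protein-coding genes only, chromosome 14 left out, and each naive WT library left out of the knockout comparison. Because the first and the second comparison share the activated WT libraries, their overlap was set beside the value for independent lists and beside 100 simulated data sets with unchanged groups.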

Results

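Gene expression was measured by RNA sequencing in 3 libraries each of naive WT, activated WT and activated CD4+ T cells of a mouse line labelled BMPR1a/CD4cre. BMPR1a is a type I receptor for bone morphogenetic proteins (BMPs), and the Cre recombinase named in the label is expressed from the Cd4 promoter in developing T cells. Between 12922 and 13395 genes per library reached 1 FPKM, and the read depth behind them is unknown. The first principal component of the tested genes held 40.8% of the variance and separated the 3 naive libraries from the 6 activated ones. The second and the third component held 10.8% and 9.8%.

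The targeted gene was examined first. Bmpr1a (ENSMUSG00000021796) lies on the minus strand of chromosome 14 at 34410734 to 34503341 in GRCm38. It was read at 0.460, 0.311 and 0.336 FPKM in the naive WT libraries, at 2.16, 2.92 and 1.40 in the activated WT libraries, and at 0.957, 1.93 and 1.20 in the activated knockout libraries. Its mean rose from 0.369 ± 0.0797 FPKM in naive to 2.16 ± 0.760 in activated WT cells (log2 fold change 1.18, SE 0.208, limma adjusted p = 0.00215). The knockout mean of 1.36 ± 0.505 FPKM was lower than that of activated WT by 0.41 on the log2 scale (log2 fold change -0.41, SE 0.208), which did not pass the test (limma adjusted p = 0.261; exact permutation p = 0.2, where 0.1 is the smallest possible), and 1 knockout library lay above 1 activated WT library. A gene-level value counts reads from all exons, including those outside a deleted part, so this measurement does not settle the genotype label in either direction. With array quality weights the difference was -0.62 and passed (limma adjusted p = 0.0385, within a range of 0.0385 to 0.579 over the alternatives).

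**Figure D1:**
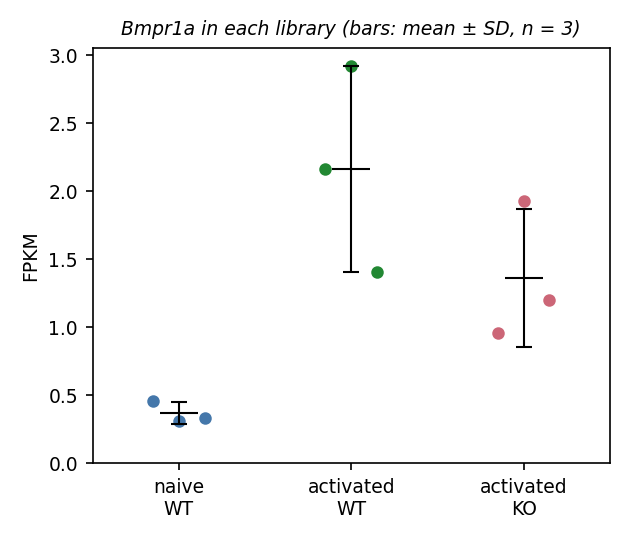
Bmpr1a expression in FPKM (vertical axis) in the 3 libraries of each group (horizontal axis). Points are libraries and black bars the mean ± SD. Naive WT libraries lie between 0.311 and 0.460, activated WT between 1.40 and 2.92, and knockout between 0.957 and 1.93.

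The comparison of activated with naive WT cells asked which transcripts differed after the 3 days of stimulation. The groups also differ in culture and in the sort, CD44-negative for naive and CD44-positive for activated cells. Stimulation cannot be told apart from these, and changes on activation below mean the whole difference between the groups. The largest rises were those of Gzmb, which encodes the cytotoxic protease granzyme B (1.08 ± 0.359 FPKM in naive cells and 340, 208 and 149 in the activated WT libraries, log2 fold change 6.74), and of Il12rb2, a subunit of the interleukin-12 receptor (0.769 ± 0.121 to 156 ± 17.3, log2 fold change 6.46). The co-inhibitory receptor genes Lag3 (log2 fold change 5.51) and Ctla4 (5.37 ± 0.890 to 283 ± 15.1 FPKM, log2 fold change 5.49), Ctla2a (log2 fold change 5.55) and the metallothionein gene Mt1 (log2 fold change 5.72) also rose. The limma adjusted p of these genes was at most 7.68e-05. Among the largest falls were Dtx1, which encodes a regulator of Notch signalling (73.4 ± 7.92 to 2.77 ± 0.583 FPKM, log2 fold change -4.31), Igfbp4 (389 ± 54.7 to 21.3 ± 7.27 FPKM, log2 fold change -4.18), the transporter gene Slc16a5 (log2 fold change -4.36) and the heat shock gene Hspa1b (log2 fold change -4.19), with limma adjusted p of at most 0.00043. In all, 7863 of 15126 genes were called by limma, 3966 higher and 3897 lower in activated cells. Of these, 1325 of the former and 624 of the latter changed at least 2-fold. The groups did not overlap at 59.35% of the tested genes, where chance gives 10%. With quantile normalization 44% of the calls were higher, against 50.4% as deposited. Of the 39 genes named by rule in this comparison, 38 were called under each of the alternatives that tested them, at most 16. Id2 was not.

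Genes of cell division rose together. All 20 members of the mitosis list rose (median log2 fold change 4.62, camera adjusted p = 5.28e-15; adjusted p = 0.421 with an estimated correlation). Examples were Ube2c, a ubiquitin-conjugating enzyme of the anaphase-promoting complex (1.25 ± 0.487 to 112 ± 33.1 FPKM, log2 fold change 5.62), Birc5, which encodes survivin (log2 fold change 5.62), and the topoisomerase gene Top2a (3.65 ± 0.891 to 175 ± 54.9 FPKM, log2 fold change 5.21). All 18 tested members of the DNA replication list rose as well (median 1.81, camera adjusted p = 5.15e-09; adjusted p = 0.514 with an estimated correlation). They included Rrm2, a subunit of ribonucleotide reductase (log2 fold change 4.64), Uhrf1 (3.72) and the thymidine kinase gene Tk1 (3.41). Of 7 CDK inhibitor and pocket protein genes, 5 rose and none fell, by camera adjusted p = 0.0213 (adjusted p = 0.423 with an estimated correlation). They included Cdkn2c (2.16 ± 0.838 to 15.6 ± 2.79 FPKM).

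Metabolic genes moved in both directions. All 17 glycolysis genes rose (median log2 fold change 2.01, camera adjusted p = 7.19e-07; adjusted p = 0.514 with an estimated correlation), led by the lactate transporter gene Slc16a3 (log2 fold change 4.28), Tpi1 (24.8 ± 3.84 to 347 ± 147 FPKM) and Pgk1 (58.9 ± 4.50 to 603 ± 215 FPKM). Of 19 cholesterol synthesis genes, 17 rose and none fell (median 0.997, camera adjusted p = 1.45e-06; adjusted p = 0.514 with an estimated correlation), among them Pmvk (log2 fold change 1.64), Fdps (1.34) and Cyp51 (1.32). Nuclear genes of oxidative phosphorylation rose in 11 of 19 cases with no fall (median 0.36, camera adjusted p = 0.00642; adjusted p = 0.646 with an estimated correlation), as in Cox5a (61.1 ± 4.67 to 115 ± 9.58 FPKM). In contrast, 12 of the 13 mitochondrially encoded genes fell over all genes and 13 adjusted over the list alone (median -0.67, camera adjusted p = 0.000262; adjusted p = 0.567 with an estimated correlation), including mt-Cytb (3186 ± 259.6 to 1450 ± 169 FPKM). Of 20 ribosome biogenesis genes, 13 fell, such as Nop56 (136 ± 6.78 to 85.1 ± 4.24 FPKM), and 3 rose, namely Wdr12, Ncl and Npm1 (median -0.47, camera adjusted p = 0.0178; adjusted p = 0.656 with an estimated correlation). Hypoxia response genes rose in 8 of 14 cases (median 1.17, camera adjusted p = 0.0216; adjusted p = 0.656 with an estimated correlation). Their levels differed within the activated WT group: Vegfa was at 21.7, 37.1 and 9.25 FPKM in libraries 1, 2 and 3. The call of this list was lost without activated WT replicate 2 and without naive WT replicate 3.

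Among T cell state genes, 14 of 19 activation markers rose (median log2 fold change 1.58, camera adjusted p = 0.000101; adjusted p = 0.402 with an estimated correlation), with Il2ra, the alpha chain of the interleukin-2 receptor (1.84 ± 0.192 to 57.9 ± 14.6 FPKM, log2 fold change 4.35), Tnfrsf4 (3.30) and Tnfrsf9 (3.14) ahead. The 14 include Cd44, the gene of the marker by which the groups were sorted. The activation markers Cd69 (52.9 ± 19.7 to 28.8 ± 2.52 FPKM) and Cd40lg (64.9 ± 6.52 to 26.6 ± 2.74 FPKM), both early markers, fell. Co-inhibitory receptor genes rose in 9 of 12 cases, and Tox fell (camera adjusted p = 0.00283; adjusted p = 0.402 with an estimated correlation). Of 22 genes of naive and quiescent T cells, 10 fell and 2 rose (median -0.46, camera adjusted p = 0.0178; adjusted p = 0.618 with an estimated correlation). Il7r fell from 190 ± 46.8 to 95.1 ± 6.03 FPKM. Satb1 was among those that rose.

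Genes of several helper lineages rose side by side. Of 14 Th1 genes 9 rose and 1, Eomes, fell (median log2 fold change 1.59, camera adjusted p = 0.000101; adjusted p = 0.386 with an estimated correlation). The lineage transcription factor gene Tbx21 went from 0.943 ± 0.368 to 29.2 ± 1.49 FPKM and the chemokine receptor gene Cxcr3 from 2.11 ± 1.02 to 61.2 ± 13.8. Of 9 Th2 genes 5 rose, among them Ccr8 (camera adjusted p = 0.00869; adjusted p = 0.386 with an estimated correlation), and of 10 follicular helper genes 7 rose over all genes and 8 adjusted over the list alone (camera adjusted p = 0.0127; adjusted p = 0.567 with an estimated correlation). Of 16 regulatory T cell genes 13 rose and 3 fell (median 1.43, camera adjusted p = 0.0015; adjusted p = 0.386 with an estimated correlation). The risers included Ctla4, Tigit (log2 fold change 4.37) and Il2ra, which effector T cells also express on activation, and the falls were Gpr83, Nt5e and Foxp3 itself (2.65 ± 0.190 to 0.958 ± 0.0805 FPKM). The Th17 list was not called, with 5 of 11 members higher and 1 lower (camera adjusted p = 0.147). Cytotoxic effector genes rose in 6 of 9 cases and Prf1 fell (camera adjusted p = 0.0178; adjusted p = 0.514 with an estimated correlation). In the same comparison rose the CD8 T cell markers Cd8a and Cd8b1. Of 7 NK cell markers Klra3, Klrd1 (21.8 ± 5.39 to 146 ± 9.24 FPKM) and Klrk1 (2.40 ± 0.354 to 29.4 ± 4.40) rose, and Klrb1c and Tyrobp fell. The NK cell list was not called (camera adjusted p = 0.362). Of 19 chemokine and trafficking receptor genes, 9 rose, or 10 adjusted over the list alone, and 2 fell (camera adjusted p = 0.0242; adjusted p = 0.514 with an estimated correlation). For the other lists called on activation, except the granulocyte and mast cell markers described with the other blood cells, the counts adjusted over the list alone equalled those over all genes.

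BMP and TGF-beta receptor and SMAD genes as a list were lower in activated WT cells: 9 of 14 fell and 2, Bmpr1a and Eng, rose (median log2 fold change -0.49, camera adjusted p = 0.0178; adjusted p = 0.514 with an estimated correlation). The falls included Acvr1b (17.8 ± 1.30 to 5.55 ± 0.423 FPKM, log2 fold change -1.52), Tgfbr3 (-0.87), Smad5 (-0.84) and Tgfbr2 (102 ± 5.25 to 59.8 ± 2.96 FPKM). Of the 4 tested BMP target genes, Runx2 (log2 fold change 2.51) and Id2 (0.61) rose, Smad7, an inhibitor of the pathway, fell (47.3 ± 3.89 to 18.5 ± 2.27 FPKM, log2 fold change -1.31), and the list was not called (camera adjusted p = 0.771). The rise of Id2 was lost under 7 of 16 alternatives, 5 of which left out 1 library (activated WT replicate 1 or 2, or any naive WT replicate; limma adjusted p between 0.00746 and 0.138 over all 16). Of 7 genes for histone H3 lysine 27 methylation enzymes, Ezh2 and Suz12 rose and the demethylase genes Kdm6a and Kdm6b fell (Kdm6b 19.0 ± 3.02 to 6.56 ± 0.666 FPKM), and the list was not called (camera adjusted p = 0.527).

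Transcripts of other blood cells also differed between naive and activated WT cells. The neutrophil genes S100a8 and S100a9 were at 21.1, 292 and 46.0 and at 28.7, 318 and 55.3 FPKM in the naive libraries 1, 2 and 3, and under 0.3 FPKM in each activated WT library. S100a8 was listed at 0 in activated WT replicate 3, as was S100a9. Lyz2, a lysozyme gene of myeloid cells, was at 14.8, 166 and 44.2 FPKM in the naive libraries and at 0.932 ± 1.32 in activated WT. Of 10 granulocyte and mast cell markers 7 fell over all genes and 8 adjusted over the list alone (camera adjusted p = 0.0216; adjusted p = 0.656 with an estimated correlation), and so did 7 of 9 macrophage and monocyte markers (camera adjusted p = 0.00283; adjusted p = 0.618 with an estimated correlation). The first of these lists lost its call with array weights and the second with the filter at a mean of 2 FPKM. Of 6 erythroid markers the 4 globin genes fell, such as Hba-a2 (24.8 ± 3.67 to 0.106 ± 0.0171 FPKM), and Hemgn rose (camera adjusted p = 0.00642; adjusted p = 0.402 with an estimated correlation). The CD8 co-receptor genes rose although the cells were sorted as CD4+: Cd8a was at 2.49, 0.0965 and 11.1 FPKM in naive and at 53.4, 52.0 and 79.3 in activated WT libraries, and Cd8b1 rose from 18.5 ± 10.7 to 121 ± 28.3 FPKM. Cd4 stood at 312 ± 23.8 FPKM in naive and 347 ± 7.78 in activated WT cells (limma adjusted p = 0.231). The list of B cell markers was not called (camera adjusted p = 0.229).

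**Figure D2:**
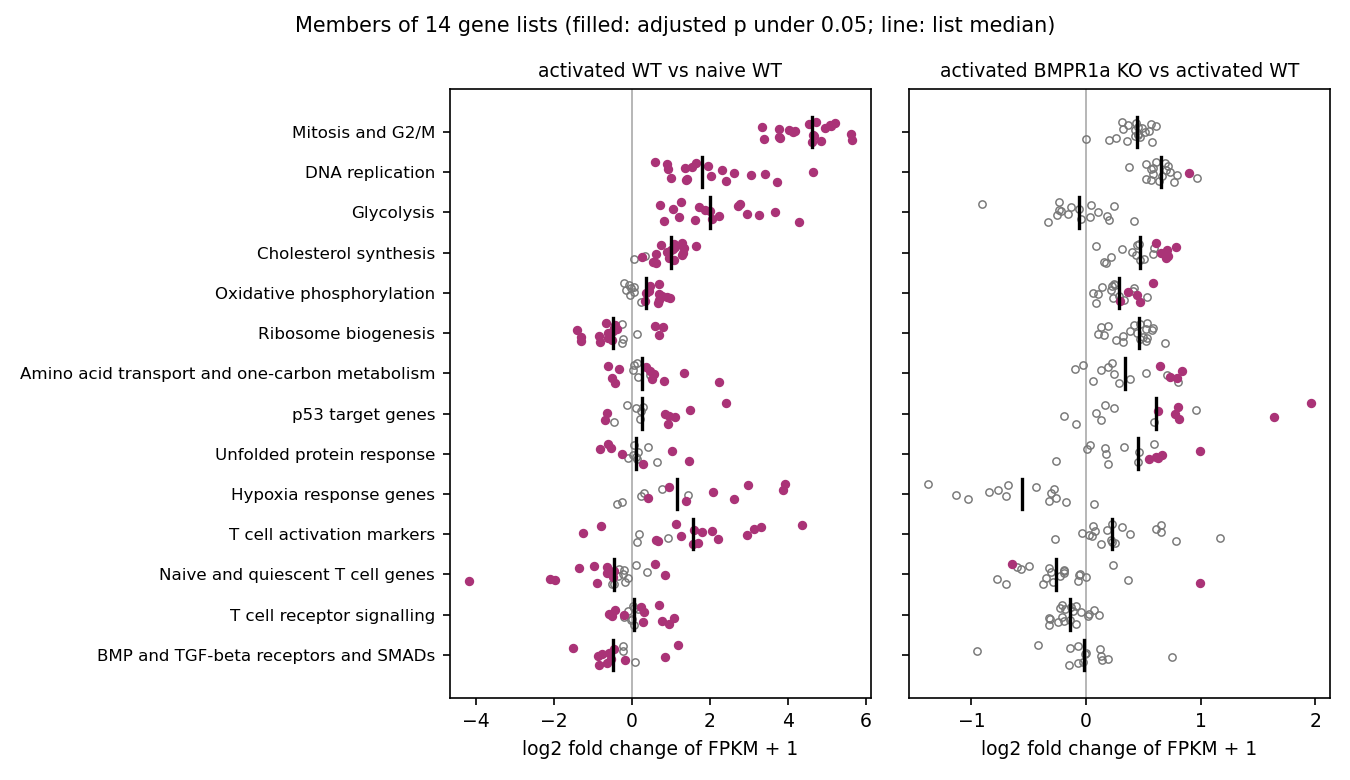
Log2 fold change of FPKM + 1 (horizontal axis) of each tested member of 14 gene lists (vertical axis), on the left for activated WT against naive WT and on the right for activated knockout against activated WT. The scales differ. Filled points passed the limma test and black lines are list medians, such as 4.62 and 0.44 for the mitosis list.

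The comparison of activated knockout with activated WT cells asked which transcripts differed with the genotype after the same culture. The lists of p53 target genes, cholesterol synthesis, oxidative phosphorylation and the unfolded protein response were called higher in the knockout, with 6 of 14, 6 of 19, 5 of 19 and 5 of 15 members passing. None of these list calls held with an estimated correlation (adjusted p = 0.506 with an estimated correlation for each). Cdkn1a, which encodes the cell cycle inhibitor p21 (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), was at 6.17 ± 2.42 FPKM in activated WT and 26.4 ± 6.96 in knockout cells (log2 fold change 1.96, SE 0.291, limma adjusted p = 0.0232). Among the genes named by rule, the largest increases were those of Mid1-ps1, Mid1, H60b, Wls and the transcript AA465934, and the largest decrease that of Ccdc22. limma called 626 of 15126 genes, 499 higher and 127 lower in the knockout, 67 and 35 of them by at least 2-fold. An unadjusted p under 0.05 was found for 3786 genes, and 416 were called with no filter on low values. The libraries of the 2 groups did not overlap at 31.19% of the tested genes, where chance gives 10%. The count and its split depended on the settings. It was 306 with median-of-ratios scaling (166 higher and 140 lower, 54.2% higher against 79.7% as deposited) and 324 with quantile normalization (56.5% higher), and it was 92 with only the 6 libraries compared and 3851 with array weights. Without activated WT replicate 1, 2 or 3 it was 283, 64 or 239, without knockout replicate 1, 2 or 3 it was 1037, 93 or 69, and without naive WT replicate 1 or 2, which enter through the shared spread, it was 143 or 407.

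List members named only where their list is described, such as Foxp3, Lag3 and Bax, were not followed singly under the alternatives. Of the 29 other gene calls named by rule in this comparison, 8 were called under each of the alternatives that tested them, at most 16. They were the higher Mid1 (5.81 ± 0.996 FPKM in activated WT and 90.7 ± 26.6 in knockout, log2 fold change 3.72, limma adjusted p = 0.000368), Mid1-ps1 (1.25 ± 0.123 and 44.3 ± 16.0), H60b, which encodes a ligand of the receptor NKG2D (0.189 ± 0.124 and 5.28 ± 0.440, log2 fold change 2.40), Wls, which encodes a protein required for the secretion of Wnt ligands (3.21 ± 0.557 and 19.2 ± 0.859, log2 fold change 2.27), and AA465934 (7.55 ± 1.06 and 35.1 ± 3.24), and the lower Ccdc22 (95.1 ± 20.3 and 17.9 ± 1.62, log2 fold change -2.33, limma adjusted p = 0.00199), Tmem254a (34.6 ± 2.28 and 12.6 ± 1.93) and Tmem254c (15 ± 0.258 and 5.06 ± 0.516). Naive WT cells had Mid1 at 7.39 ± 0.981, H60b at 0.110 ± 0.0641, Wls at 3.27 ± 0.714 and Ccdc22 at 125 ± 26.4 FPKM. Mid1 (ENSMUSG00000035299) on chromosome X (169685199 to 170005736) has the near-identical copy Mid1-ps1 on Y (90753057 to 90763485), and Tmem254a and Tmem254c have close copies next to them on chromosome 14, so their values are uncertain. Ccdc22 (ENSMUSG00000031143, X, 7593809 to 7605517, minus strand) overlaps the end of Foxp3 (ENSMUSG00000039521, X, 7573644 to 7595245, plus strand). Ppp1r3f, chosen after its values were seen, overlaps the other end of Foxp3 and was lower too (log2 fold change -1.085, limma adjusted p = 0.0282). Mid1-ps1, H60b, AA465934, Ccdc22, Tmem254a and Tmem254c each lie within 0.5 Mb of another 2-fold knockout call. Their stability therefore does not tell loss of BMPR1a from other differences between the mouse lines. The genes whose call was lost under at least 1 alternative were, among the higher ones, Cdkn1a, Ifi44 (2.24 ± 1.12 and 10.4 ± 4.37 FPKM) and Penk (1.02 ± 0.440 and 5.72 ± 2.76), and among the lower ones Ajuba (27.6 ± 2.24 and 9.31 ± 3.29), Slc26a11 (6.90 ± 1.11 and 1.96 ± 0.625), Slco1a6 (11.4 ± 2.27 and 3.17 ± 0.859), Hmgb1-ps8, a pseudogene within H60b, and mt-Ta, a mitochondrial tRNA gene whose short length makes its FPKM unstable.

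The p53 target list was higher in the knockout (median log2 fold change 0.61, camera adjusted p = 0.000743; adjusted p = 0.506 with an estimated correlation). Of 14 tested members 6 were called over all genes and 8 adjusted over the list alone, none of them lower: Phlda3 (2.18 ± 0.577 and 9.0 ± 2.49 FPKM, log2 fold change 1.64), Ccng1 (50.8 ± 4.51 and 79.0 ± 7.93), Cdkn1a, Zmat3 (3.61 ± 0.292 and 7.15 ± 1.15), Sesn2 (3.59 ± 0.130 and 6.94 ± 1.30) and the pro-apoptotic Bax (66.6 ± 5.21 and 117 ± 9.83, log2 fold change 0.80) were those called over all genes. Mdm2, another target, did not pass (35.7 ± 1.62 and 40.2 ± 1.94 FPKM, limma adjusted p = 0.29). Apoptosis regulators were higher as a list (median 0.23, camera adjusted p = 0.0366; adjusted p = 0.506 with an estimated correlation) with 2 of 18 members called over all genes and 4 adjusted over the list alone. The 2 were Bax and the anti-apoptotic Bcl2l1 (12.5 ± 0.910 and 24.8 ± 2.00 FPKM, log2 fold change 0.93). This list lost its call without knockout replicate 1, activated WT replicate 1 or activated WT replicate 3, with array weights and with the filter at 2 FPKM. The call of Cdkn1a was lost under 4 of 16 alternatives, among them those without knockout replicate 2 or 3 and with the 6 libraries alone (limma adjusted p 0.00532 to 0.0982).

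**Figure D3:**
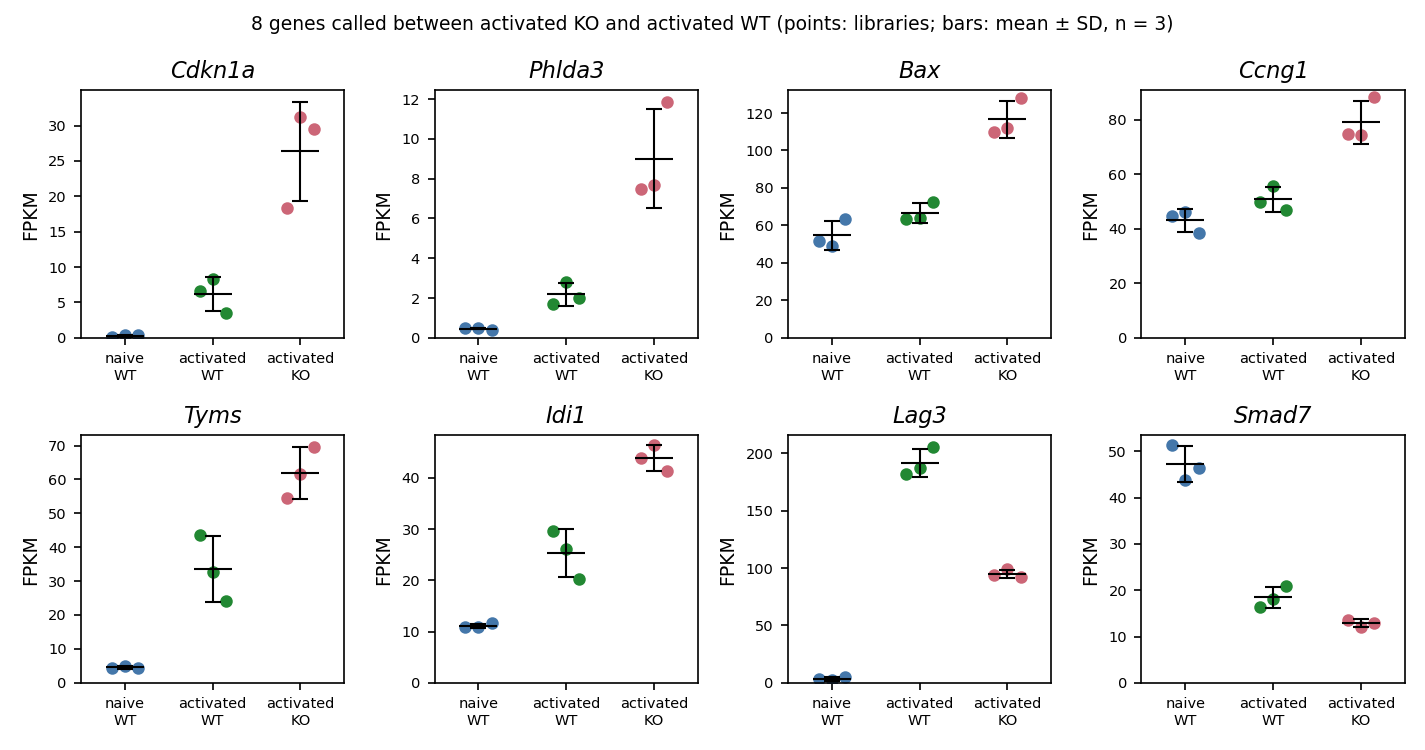
FPKM (vertical axes, each from 0) of 8 genes called between activated knockout and activated WT, in the 3 libraries of each group. Points are libraries and black bars the mean ± SD. The knockout libraries lie above every activated WT library for Cdkn1a, Phlda3, Bax, Ccng1, Tyms and Idi1 and below every one for Lag3 and Smad7.

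Lists of proliferation and biosynthesis genes were called higher in the knockout, with few single genes passing. All 18 DNA replication genes had a positive log2 fold change (median 0.65, camera adjusted p = 4.12e-07; adjusted p = 0.506 with an estimated correlation). Only Tyms, the thymidylate synthase gene, passed over all genes (33.5 ± 9.74 and 61.9 ± 7.65 FPKM, log2 fold change 0.90, limma adjusted p = 0.0483), and all 18 passed adjusted over the list alone. The call of Tyms was lost under 11 of 16 alternatives, among them those without any 1 of the knockout replicates 1, 2 and 3 or without activated WT replicate 2 or 3 (limma adjusted p up to 0.172). Median-of-ratios scaling and quantile normalization were among them too. The mitosis list was called higher with no member passing (median 0.44, 19 of 20 positive, camera adjusted p = 0.00429; adjusted p = 0.821 with an estimated correlation), a call that was lost without activated WT replicate 3. Of 19 cholesterol synthesis genes 6 passed over all genes and 15 adjusted over the list alone, all higher (median 0.47, camera adjusted p = 9.79e-07; adjusted p = 0.506 with an estimated correlation), as in Idi1 (25.3 ± 4.74 and 43.9 ± 2.56 FPKM), Hsd17b7 (2.99 ± 0.452 and 5.54 ± 0.460) and Sqle (19.4 ± 3.75 and 32.0 ± 3.26). Oxidative phosphorylation genes had 19 of 19 positive fold changes, with 5 called over all genes and 16 adjusted over the list alone (median 0.29, camera adjusted p = 1.92e-06; adjusted p = 0.506 with an estimated correlation). Ndufa4 stood at 135 ± 5.29 and 203 ± 19.9 FPKM, Atp5b at 383 ± 25.3 and 532 ± 41.1, and Cyc1 at 56.4 ± 3.43 and 77.3 ± 4.12. Ribosome biogenesis genes had 20 of 20 positive fold changes and none called over all genes, but 16 adjusted over the list alone (median 0.46, camera adjusted p = 1.92e-06; adjusted p = 0.506 with an estimated correlation). In the list of amino acid transport and one-carbon metabolism 4 of 16 genes were called higher, and 10 adjusted over the list alone (camera adjusted p = 0.000622; adjusted p = 0.506 with an estimated correlation): Phgdh (45.3 ± 6.72 and 81.7 ± 13.6 FPKM), Mthfd1, Shmt2 and Slc7a1. Of 15 unfolded protein response genes 5 were called higher, and 7 adjusted over the list alone (camera adjusted p = 0.00114; adjusted p = 0.506 with an estimated correlation): Pdia6 (39.5 ± 1.14 and 63.5 ± 9.61 FPKM), Creld2, Sdf2l1, Calr and Manf. Each of Idi1, Hsd17b7, Sqle, Ndufa4, Atp5b, Cyc1, Phgdh, Mthfd1 and Shmt2 lost its call under 5 to 11 of 16 alternatives, always including those without knockout replicate 2, without knockout replicate 3 and without activated WT replicate 2 (limma adjusted p up to 0.157). Ndufa4, Atp5b, Sqle and Phgdh also lost it without activated WT replicate 3, and Cyc1, Hsd17b7 and Shmt2 without activated WT replicate 1 and without replicate 3. Hsd17b7, Sqle and Shmt2 lost it with median-of-ratios scaling and with quantile normalization as well, and Atp5b with median-of-ratios scaling. Glycolysis genes were not called as a list (median -0.06, camera adjusted p = 0.26).

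Lower in the knockout were the lists of naive T cell genes, T cell receptor signalling, hypoxia response genes and cytosolic ribosomal proteins. In the first, 19 of 22 genes had a negative log2 fold change (median -0.26, camera adjusted p = 0.000132; adjusted p = 0.506 with an estimated correlation), while Ramp3 was called higher (4.27 ± 0.728 and 9.48 ± 1.42 FPKM). The call of Ramp3 was lost under 4 of 16 alternatives, namely with the 6 libraries alone, without knockout replicate 2, without knockout replicate 3 and without activated WT replicate 2 (limma adjusted p up to 0.0969). Of 19 T cell receptor signalling genes 15 were negative and none was called by limma (median -0.14, camera adjusted p = 0.000203; adjusted p = 0.506 with an estimated correlation). The hypoxia list was negative in 13 of 14 cases, none of them called (median -0.56, camera adjusted p = 0.000622; adjusted p = 0.656 with an estimated correlation). Its genes were spread within groups, with Vegfa at 6.98, 15 and 2.92 FPKM in the knockout libraries. The ribosomal protein list shifted by a median of -0.10 with no member called (camera adjusted p = 0.00603; adjusted p = 0.821 with an estimated correlation), and its call was lost without activated WT replicate 1 and with quantile normalization, under which the median was 0.001.

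Of the BMP target genes, Smad7 was lower in the knockout (18.5 ± 2.27 and 12.8 ± 0.859 FPKM, log2 fold change -0.49, SE 0.102, limma adjusted p = 0.0439), and Id2 (49.6 ± 8.60 and 69.4 ± 22.2 FPKM), Id3 (28.8 ± 8.03 and 28.2 ± 7.78) and Runx2 (7.14 ± 1.61 and 9.51 ± 0.973) did not pass. The list was not called (camera adjusted p = 0.845), nor was that of receptors and SMADs, in which none of 14 members passed (median -0.02, camera adjusted p = 0.444). The call of Smad7 was lost under 8 of 16 alternatives, including those without knockout replicate 2 or 3 or activated WT replicate 2 or 3 (limma adjusted p 0.00823 to 0.151). Of the TGF-beta family ligand genes, Tgfb1 was higher (54.7 ± 1.44 and 67.3 ± 3.12 FPKM).

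Helper lineage lists did not pass between the genotypes, although single members did. Among 16 regulatory T cell genes, Foxp3 (0.958 ± 0.0805 and 4.14 ± 1.85 FPKM, log2 fold change 1.32, limma adjusted p = 0.0351) and Ikzf2 (3.68 ± 0.158 and 6.78 ± 1.87) were higher, and the list was not called (camera adjusted p = 0.0914). Both groups had been sorted as negative for the Foxp3 reporter, and Foxp3 overlaps Ccdc22. Eomes of the Th1 list (1.83 ± 0.227 and 4.53 ± 1.23 FPKM) and Il1rl1 of the Th2 list (0.405 ± 0.0987 and 2.19 ± 0.798) were higher as well. The camera adjusted p was 0.845 for the Th1 list, 0.444 for Th2, 0.291 for Th17 and 0.323 for follicular helper genes. The cytokine list was called higher (median 0.65, 15 of 16 positive, camera adjusted p = 0.00333; adjusted p = 0.506 with an estimated correlation) with Tnfsf11, which encodes RANKL, as the single call over all genes (1.48 ± 0.405 and 5.35 ± 0.699 FPKM) and 6 calls adjusted over the list alone. Lag3 was lower (191 ± 12.4 and 95.2 ± 3.5 FPKM, limma adjusted p = 0.0478), and the granzyme gene Gzmc was higher (6.21 ± 2.07 and 20 ± 6.77). The calls of single genes in this paragraph were not followed under the alternatives. Markers of CD8 T cells did not pass between the genotypes, with Cd8a at 74.9, 105 and 107 FPKM in the knockout libraries (limma adjusted p = 0.647).

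Activation-response genes among the knockout calls numbered 352 of 626, where independent lists of these sizes would share 325.4. By direction, 166 genes were higher in both comparisons (130.8 for independent lists), 51 rose on activation and were lower in the knockout (33.3), 111 fell on activation and were higher in the knockout (128.6), and 24 were lower in both (32.7). Because activated WT libraries enter both comparisons with opposite sign, chance alone makes the fold changes covary negatively: the covariance was -0.0983, against -0.132 on average over 100 simulated data sets with unchanged groups, so the difference was 0.0333. Simulated unchanged groups shared at most 1 call, but they hold no changed genes, so this count is no measure for the 352. The value to set beside it is the 325.4 of independent lists. The 3 shared libraries cannot be split into 2 sets of at least 2, and part of the excess or deficit in each direction may come from them. The shared count moved with the settings as the number of knockout calls did: it was 41 with only the 6 libraries compared, 2733 with array weights, 174 with median-of-ratios scaling, 188 with quantile normalization and 207 with no filter. Without knockout replicate 1, 2 or 3 it was 835, 83 or 64, without activated WT replicate 1, 2 or 3 it was 172, 34 or 132, and without naive WT replicate 1 or 2 it was 67 or 222.

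Compared with naive WT cells, activated knockout cells showed much of the same response as activated WT cells. limma called 8603 genes, 4810 higher and 3793 lower, and 6699 of these were also called between activated and naive WT (4472 for independent lists). Of the shared genes 3591 were higher and 3090 lower in both, and 18 were not of the same direction, 11 of them lower and 7 higher in the knockout comparison. The covariance of the fold changes was 0.859, against 0.130 in simulated unchanged groups sharing the naive libraries. With quantile normalization 43.9% of the calls were higher, against 55.9% as deposited. In this comparison too, Bmpr1a was higher in the activated cells (log2 fold change 0.77, limma adjusted p = 0.0142).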

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

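The alternatives with protein-coding genes only, chromosome 14 left out, and each naive WT library left out of the knockout comparison were chosen after seeing the data. No named gene and no list passed its test in the opposite direction under an alternative. The counts of genes called between activated and naive WT and between knockout and naive WT stayed within 1.5 times of the full count under every alternative (6702 to 7744 and 7415 to 8407 with a library left out). The count between knockout and activated WT, 626, was 92 with the 6 libraries of the comparison alone, 3851 with array weights, 306 with median-of-ratios scaling, 324 with quantile normalization and 416 with no filter, and ran from 64 to 1037 with a library left out. Leaving out chromosome 14 gave 514 and protein-coding genes alone 900. The activation-response genes among these calls, 352, numbered 41, 2733, 174, 188 and 207 under the same first 5 alternatives and 34 to 835 with a library left out. Array weights ranged from 0.414 to 4.05, with naive WT replicate 1 weighted most. The cause of these shifts was not tested, except that the 6 libraries alone estimate the spread from fewer samples. Bmpr1a between knockout and activated WT passed with array weights (-0.62) and not otherwise (-0.60 to -0.24 with a library left out). The filter at 2 FPKM removes it. With correlations estimated per list, 0 lists were called in both comparisons, where unadjusted camera p under 0.05 remained for 3 lists on activation and 2 in the knockout. The other alternatives gave 21 to 24 and 12 to 21 lists. In simulated data with 1 list only, Glycolysis, shifted by 0.5 on the log2 scale, the estimated correlation called it in 13 of 20 data sets and the preset one in 20. Genes were drawn independently in these data sets, whereas the correlation estimated in the real lists had a median of 0.26. The simulation therefore cannot show whether list calls with the preset correlation are false when genes are correlated. Other lists and shifts were not simulated. Over the genes named by rule and the alternatives, 319 results in the knockout comparison stayed past the threshold and 144 did not. On activation 616 stayed and 7 did not. List members named only where their list is described are not in these counts.

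Whether the replicate numbers pair the libraries is not settled. Deviations from the group means correlated at 0.003 to 0.054 over the 9 pairs of libraries of the same number, all positive. Over the 18 other pairs they correlated at -0.068 to 0.038, with both signs. The correlations are weak, but a structure shared by libraries of the same number is not excluded. With the replicate block, 58 genes were called between knockout and activated WT, 57 of them among the 626, and 25 activation-response genes were among them. With the block Cdkn1a, among other named genes, was not called between knockout and activated WT, and the block moved no other count by over 1.5 times. Depth is unknown, so what it limits cannot be stated.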

Other observations

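In this part, the tests on positions, B cell markers, scaling and activated WT replicate 3 were chosen after the result was seen, and the expectations for the counts over other splits were written down after these had been seen. The second list of neutrophil genes was chosen after the first list had been seen and before its own values were.

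Some lists that were not called between activated and naive WT held single genes that passed. Of 20 interferon-stimulated genes 8 fell and 3 rose on activation (median log2 fold change -0.52, camera adjusted p = 0.133). Ifit1 fell from 19.9 ± 1.99 to 6.75 ± 2.31 FPKM, whereas the signal transducer gene Stat2 rose. In the knockout comparison 18 of the 20 were positive and Ifi44 alone was called (camera adjusted p = 0.109). Of 17 immediate early genes 6 fell on activation, Fos, Egr1 and Dusp1 among them, and 3 rose (camera adjusted p = 0.602). Of 10 heat shock genes Hspa1a, Hspa1b and Dnajb1 fell and none rose (camera adjusted p = 0.207). Hspa1b was at 9.31, 52.6 and 18.6 FPKM in the naive libraries. Among genes chosen after their values were seen, the metallothionein gene Mt2 rose with Mt1 (0.195 ± 0.0441 to 48.2 ± 30.7 FPKM), and Slc30a1, a zinc exporter gene, fell (log2 fold change -1.39).

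The values of 3 effector genes, picked after their values were seen, were uneven among the knockout libraries, and differences between libraries were not tested. Il17a was at 33.5, 12.5 and 2.87 FPKM in knockout replicates 1, 2 and 3 and between 1.26 and 3.30 in activated WT. Ifng was highest in replicate 2, at 4.64, 34.4 and 6.64 FPKM, as was Gzmb with 205, 1054 and 262, against 340, 208 and 149 in activated WT. None of these passed between the genotypes (limma adjusted p = 0.162 for Il17a, 0.138 for Ifng and 0.439 for Gzmb). The gamma-delta T and innate lymphoid list was not called in the knockout (camera adjusted p = 0.0914), and Tcrg-C2 alone of its members passed (0.897 ± 0.193 and 3.52 ± 0.444 FPKM).

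Knockout calls lay near each other in the genome. Leaving out antigen receptor genes, 20 of 89 placed calls of at least 2-fold had another within 0.5 Mb, above the median of 8 and the 95th percentile of 14 over 10000 equal draws from the 2-fold activation calls, so genome segments or insertions that differ between the mouse lines may contribute. Among the 20 were the named genes H60b, Hmgb1-ps8, AA465934, Tmem254a, Tmem254c, Ifi44, Ccdc22 and Mid1-ps1, and also Foxp3 and Ppp1r3f beside Ccdc22. Without pseudogenes, overlapping genes and pairs of 1 family the count of such calls was 6, equal to the median of equally treated draws. This step also removes neighbours that a duplicated or inserted segment would give, so the lower count does not tell shared reads from such segments. Reads shared between copies or overlapping genes stay open as a source. On chromosome 14, 36 of 473 genes were called (7.61%), against 4.04% elsewhere (Fisher's exact p = 0.000575), while activation calls did not differ there (p = 0.241). Within 20 Mb of Bmpr1a 9.63% were called and beyond it 6.32% (Fisher's exact p = 0.215), so a segment around the targeted gene cannot be told apart from a wider difference. Loss of BMPR1a itself stays open for all of these genes, since no naive or other control of the knockout line was analysed here.

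Granulocyte and myeloid genes were highest in naive WT replicate 2. B cell markers were lower there than in the other naive libraries by a median of -2.19 on the log2 scale. They went in the same direction in 14 of 14 cases, and the median lay below all of 10000 matched random lists. The random lists drew genes independently, whereas these markers vary together (correlation estimated for the list 0.829). The rank among random lists therefore does not measure how unusual the difference is for 1 library. The lower values of the markers argue against added B cells in that library. They cannot decide whether the share of T cells was lower, since other cells could lower that share without B cells. RNA of granulocytes may be a source: in a second list of neutrophil genes 15 of 16 were higher in that library, with a median of 1.58 that exceeded all matched random lists. Only members with a mean of at least 0.5 FPKM over the 9 libraries were used, that library included. Some passed only through their high value there, such as Wfdc21 at 6.58 FPKM, against at most 0.975 in any other library. The selection thus favours the count and the median, and the random lists again drew genes independently. Lcn2 was at 1.37, 18.2 and 1.97 FPKM and Chil3 at 1.61, 13.7 and 1.69. The most abundant of the first list, S100a9, reached 318 FPKM, close to Cd4 at 319 in the same library, although the sort for CD4 would remove such cells. No biological explanation was tested, since the labels set that library apart from its group in no way.

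Most knockout calls were higher than in activated WT. The size factors of the knockout libraries, 1.017 to 1.035, all lay above those of the activated WT libraries, 0.971 to 0.982. With median-of-ratios scaling 54.2% were higher instead of 79.7%. This scaling centres the fold changes, so the test decides nothing about scaling between libraries as a source. Without activated WT replicate 3 the share was 54.4%, where leaving out any other activated library gave between 69.9% and 78.1%. The median log2 fold change of all tested genes was not lower without it, at 0.071 against 0.058, so this library as the source is left open. A broad rise of expression in the knockout was not tested and stays open.

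For the 3 counts of called genes, the 6 libraries of a comparison make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 7863 genes between activated and naive WT, and the highest of the other splits 5. It called 626 between knockout and activated WT, against at most 4 for another split, and 8603 between knockout and naive WT, against at most 4. In each comparison 1 of the 10 splits, the real one, called as many.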
